A study of Mus musculus with 4 samples.

How the data were processed

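The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) from CD4+ T cells of C57BL/6 mice. It lists 4 samples with 1 library in each group, namely an antibody ChIP, a biotin ChIP and an input library for each. In the antibody ChIP, DNA bound by Foxo1 was recovered with an antibody against Foxo1, per the labels. In the biotin ChIP, cells came from mice that carry a tagged Foxo1 together with BirA, a bacterial ligase that attaches biotin to its tag, and the bound DNA was recovered on streptavidin, a protein that binds biotin tightly. Libraries were sequenced on an Illumina Genome Analyzer, per the labels' protocols.

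Peak lists stand behind 3 of the samples, and no list of the biotin input was used here. Per the submitters' processing notes, CASAVA 1.4 and Bowtie 0.12.7 were used and positions refer to the mouse genome build mm9. The peak caller and its settings are not given in the sources used here. The names of both ChIP lists state a false discovery rate of 0.05. Each list gives, per peak, the position, the width, a fold, a p-value and a summit, per the file headers. The fold is a linear ratio as deposited by the authors, and what it is relative to is not given in the sources used here. It was therefore used to describe, rank or filter peaks within a list, and its levels were not compared between lists. The 1 exception in which folds of both lists enter a test is their correlation over the shared pairs, which does not depend on a common scale. The p-value of each peak was likewise the authors' own value as deposited. It was listed as 0 for 406 of 2507 antibody peaks and 145 of 723 biotin peaks. The largest deposited p-value was 7.49e-12 in the antibody list and 9.76e-12 in the biotin list. Every p-value above 0 and under 1e-12 (1777 antibody and 469 biotin peaks) was a whole multiple of 1.11e-16, the step of double-precision numbers just below 1, within a tolerance of 0.01 of a step. P-values of this size cannot order the strongest peaks, so peaks were ranked by fold. The list attached to the antibody input had no header line, and its columns were read in the order of the ChIP lists. Read counts and library sizes were not part of the lists, so the depth behind each peak is unknown.

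Summits never fell on a start position and fell on the end position of 58 antibody and 10 biotin peaks, which is the pattern of starts counted from 0 and summits counted from 1. Starts were raised by 1 throughout, so that printed positions count from 1. Peaks were compared by overlap of at least 1 bp. The overlap was tested, one-sided, against 1000 circular shifts of the biotin peaks along each chromosome, within the span between the outermost peaks of both lists. This null ignores chromatin accessibility and mappability. Folds and widths of peaks with and without an overlap were compared within each list by a two-sided permutation test of the difference in medians (100000 resamples), with Benjamini-Hochberg adjustment over the 4 tests. Chromosome counts were compared by Fisher's exact test. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error over peaks only. Peaks are not replicates, and with 1 library per group every test compares the lists at hand and not the conditions.

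The alternatives were other definitions of a shared peak (50% of the shorter peak, centres within 200 bp, peaks within 1000 bp), the top 50% and top 25% of each list by fold, another random placement, chromosome X left out, and comparison within 3 groups of similar width. These choices, the tests and the rule for named peaks were fixed before the data were examined, with peaks ordered by a score. Fold was taken as that score after the deposited p-values had been seen. Local shifts of 200 kb to 1 Mb, an antibody list of the same length as the biotin list, and lists without peaks that have a neighbour within 1000 bp were added after seeing the data, as were the bins by fold, the correlation of paired folds, the peak densities per chromosome and the chromosome comparison without shared peaks. The overlap test was tested on 20 pairs of simulated lists with 2507 and 722 peaks. With 200 shared peaks planted, it found 200 to 201 and passed the 0.05 threshold in all 20 pairs, and with none planted it passed in 0. Planted peaks had the same start as an antibody peak, and all others were placed at random, without the clustering of the real lists. Fewer shifts were used than in the main test. The simulation therefore checks the calculation and not the error rate in these data. The fold test on 2507 simulated antibody peaks, with a fold of 4 added to the shared ones, passed in 20 of 20 simulations and recovered a mean difference of 3.84. Without the addition it passed in 0.

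By the rule for named peaks, the 10 peaks with the highest fold in the antibody list, in the biotin list and, by antibody fold, among shared peaks are named by position. The gene table at hand follows another build (GRCm38), and positions were not converted between builds, so peaks carry no gene names, and promoter shares, motif counts and gene lists were not analysed here. For the same reason it is not stated whether a peak lies in an exon, an intron or a UTR. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.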

Results

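The genomic binding sites of Foxo1, a forkhead transcription factor that acts in the homeostasis and differentiation of T lymphocytes, were mapped in mouse CD4+ T cells by ChIP-seq. The protein was isolated in a pair of ways, with an antibody against the endogenous protein in C57BL/6 mice and by streptavidin capture of a biotinylated, tagged Foxo1. The antibody ChIP list held 2507 peaks on 20 chromosomes and covered 236684 bp. The biotin ChIP list held 723 peaks on 21 chromosomes, the mitochondrial one included, and covered 68000 bp. Antibody peaks had a median width of 90 bp (interquartile range 61 to 118 bp) and biotin peaks one of 84 bp (54.5 to 117 bp). The fold given by the authors had a median of 9.43 in the antibody list (range 3.01 to 57.6) and of 5.61 in the biotin list (range 2.03 to 48.3). Each group was a single library, so no value carries a replicate error, and the sequencing depth is unknown.

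The main comparison of the design asks how far the sites recovered by both isolation methods coincide. Of the 2507 antibody peaks, 341 overlapped a biotin peak (13.6%, 95% interval 12.3 to 15.0%). These met 341 of the 723 biotin peaks (47.2%, 43.5 to 50.9%), and each shared peak had exactly 1 partner. Circular shifts of the biotin peaks gave a mean of 0.134 shared peaks and at most 2, so the overlap exceeded each of the 1000 shifts (one-sided permutation p = 0.001, the smallest that these shifts can give). When the antibody list was restricted to its 723 peaks of highest fold, 245 of them were shared (33.9%, 30.4 to 37.5%). Both percentages rest on the same 341 pairs and differ through the lengths of the lists.

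Shared peaks had higher folds than unshared peaks in both lists. In the antibody list, shared peaks had a median fold of 18.2 (interquartile range 11.3 to 26.3, n = 341) against 8.85 (6.80 to 11.9, n = 2166) for peaks without a biotin partner. The difference of 9.32 passed a two-sided permutation test (p = 1e-05, adjusted p = 2e-05 over 4 tests, the smallest that the resamples allow). In the biotin list the medians were 6.82 (4.84 to 9.11, n = 341) and 5.08 (3.97 to 6.18, n = 382), a difference of 1.74 (permutation p = 1e-05, adjusted p = 2e-05). The shared fraction of antibody peaks was 58.0% (51.6 to 64.2%) in the 10% of peaks with the highest fold, 27.5% (22.1 to 33.5%) in the next 10% and 0.797% (0.0966 to 2.85%) in the 10% with the lowest fold. Among biotin peaks it was 80.6% (69.5 to 88.9%) in the highest 10% and 24.7% (15.3 to 36.1%) in the lowest. Between these ends the biotin fractions did not fall steadily, with 30.6% (20.2 to 42.5%) in the fifth bin and 44.4% (32.7 to 56.6%) in the eighth.

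**Figure D1:**
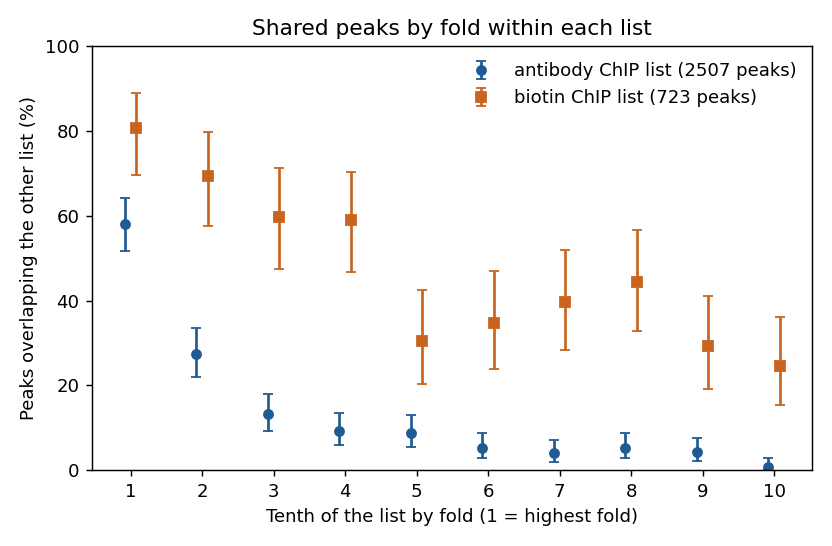
Percentage of peaks that overlap a peak of the other list, for 10 bins of each list by fold (bin 1 holds the highest folds); circles are antibody peaks, squares are biotin peaks, and bars are exact 95% binomial intervals over peaks. The fraction reaches 58.0% and 80.6% in the highest bins of the antibody and biotin lists and 0.797% and 24.7% in the lowest bins.

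The 10 antibody peaks with the highest fold were all shared. The highest lay on chromosome 3 (96361724 to 96361742, mm9) with a fold of 57.6, and its biotin partner (96361705 to 96361820) had a fold of 15.3. On chromosome 2, a peak at 19579284 to 19579384 had an antibody fold of 53.2 and a biotin fold of 19.9. A peak on chromosome 13 (81025530 to 81025590) had folds of 52.5 and 13.7, and one on chromosome 5 (87233281 to 87233287) had folds of 52.4 and 17.3. The peaks of this chromosome 5 pair overlapped by 2 bp, less than 50% of the shorter peak, the antibody peak of 7 bp. The site on chromosome 14 (8930624 to 8930710) was high in both lists, with an antibody fold of 51.1 and a biotin fold of 40.4. The site on chromosome 8 (87502787 to 87502811) likewise had an antibody fold of 51.0 and a biotin fold of 22.7. The other 4 lay on chromosome 15 (79758207 to 79758336), chromosome 6 (31166494 to 31166609), chromosome 7 (52104438 to 52104541) and chromosome 11 (86621157 to 86621183). Their antibody folds ran from 46.6 to 48.6, and their biotin folds were 13.8, 15.0, 7.15 and 11.4, in that order of chromosomes.

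Of the 10 biotin peaks with the highest fold, 6 were shared. These included the sites on chromosomes 14 and 8 named above and a peak on chromosome 4 (33334834 to 33334941) with a biotin fold of 37.0 and an antibody fold of 44.6. A peak on chromosome 16 (4559826 to 4559833) had a biotin fold of 23.0 and an antibody fold of 15.1. The remaining shared sites lay on chromosome 17 (23757575 to 23757613), with a biotin fold of 22.7 and an antibody fold of 22.1, and on chromosome 11 (68908318 to 68908364), with folds of 21.7 and 42.1. The peaks of this chromosome 11 pair overlapped by 7 bp, less than 50% of the shorter peak. The 4 unshared peaks formed close pairs on chromosome 17. One pair lay at 39982236 to 39982545 and 39985257 to 39985720 with the highest folds of the biotin list, 48.3 and 40.5, and the nearest antibody peak was 2893513 bp away. Whether any of these 4 peaks lies in sequence present in many copies, such as ribosomal DNA, was not analysed here, so their folds cannot be read as the strongest binding of the tagged protein. The other pair lay at 36368266 to 36368319 and 36368448 to 36368453, with folds of 28.0 and 30.5, and the nearest antibody peak was 4084 bp from it with a fold of 4.42. Among the 50 peaks with the highest fold, 41 antibody peaks and 40 biotin peaks were shared, and 21 pairs stood in the top 50 of both lists.

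Within the 341 shared pairs, summits lay close together and folds were correlated. The median distance between summits was 20 bp (interquartile range 11 to 38 bp), and 277 pairs (81.2%) had summits within 50 bp of each other. Pairs were chosen by overlap of narrow peaks, which by itself keeps summits close. No distance expected from overlap alone was computed, so this closeness is not separate evidence of agreement. Folds of the 341 pairs correlated across peaks, with Pearson's r = 0.55 on log2 folds and Spearman's rho = 0.53 (two-sided permutation p = 1e-05 for each, the smallest that the resamples allow, and Benjamini-Hochberg adjusted p = 1e-05 over this pair of tests). Peaks of one genome are not independent replicates, and pairs below the calling threshold of either list are not part of this correlation.

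**Figure D2:**
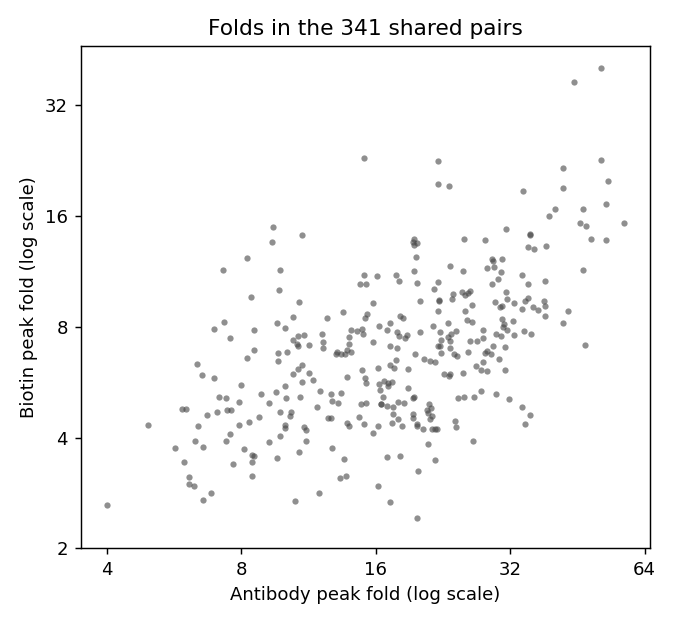
Antibody fold (x axis, log scale) and biotin fold (y axis, log scale) of the 341 shared pairs, with 1 point per pair. Folds rise together across pairs (Spearman's rho = 0.53).

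**Figure D3:**
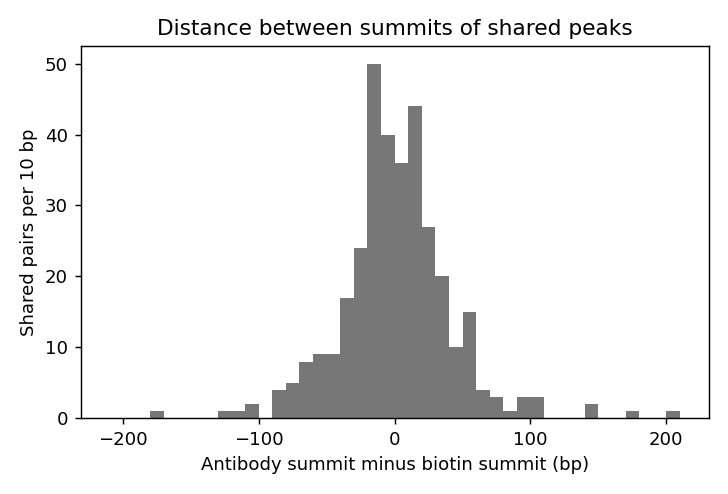
Antibody summit position minus biotin summit position, in bp, for the 341 shared pairs, in bins of 10 bp. The offsets centre near 0, and 277 pairs lie within 50 bp. Overlap of narrow peaks, by which the pairs were chosen, by itself limits these offsets.

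The antibody peaks of highest fold without a biotin partner, chosen after their values were seen, were on chromosome 2 (24775168 to 24775249, fold 46.5), chromosome 11 (54769629 to 54769735, fold 42.2) and chromosome 8 (72758355 to 72758441, fold 40.7). Their nearest biotin peaks lay 56314, 831231 and 609114 bp away. They ranked 11, 16 and 20 in the antibody list.

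Peak width did not separate shared from unshared peaks at the 0.05 threshold. Shared antibody peaks had a median width of 87 bp against 90 bp for unshared ones, a difference of -3 bp (two-sided permutation p = 0.355, adjusted p = 0.355). Shared biotin peaks had a median width of 86 bp against 81 bp, a difference of 5 bp (permutation p = 0.186, adjusted p = 0.249). The unadjusted p fell below 0.05 under 3 other definitions of a shared peak, with differences of -7 and -8 bp in the antibody list and 8 bp in the biotin list. With an overlap of 50% of the shorter peak, the antibody difference was 0 bp.

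The largest share of biotin peaks was on chromosome 11 (64 peaks, 8.85%), which held 183 antibody peaks (7.30%). Chromosome 5 held the most antibody peaks (187, 7.46%) and 54 biotin peaks (7.47%). Fisher's exact test found 0 of 21 chromosomes that differed between the lists, at an adjusted p under 0.05 or an unadjusted one (smallest unadjusted p = 0.107). The 341 shared sites count in both lists and draw their shares together. Among unshared peaks alone (2166 antibody, 382 biotin), 0 chromosomes passed Fisher's exact test at an adjusted p under 0.05 and 1 did unadjusted, chromosome 13, with 3.83% of antibody and 1.57% of biotin peaks (p = 0.0231, adjusted p = 0.485). Peaks per Mb, taken over the span between the outermost peaks of a chromosome, ranged from 0.289 on chromosome X to 1.62 on chromosome 19 in the antibody list. In the biotin list they ranged from 0.0723 on chromosome X to 0.542 on chromosome 11. Across the 20 chromosomes with peaks in both lists, the densities correlated with Pearson's r = 0.84 (permutation p = 3e-05) and Spearman's rho = 0.89 (permutation p = 1e-05). Pearson's r was 0.82 without chromosomes 19 and X, which lay farthest from the median antibody density. Shared sites count in both densities, so part of this correlation is built in. Both densities of a chromosome are also divided by the same span, which by itself can make them correlate. This applies to unshared peaks as well, and the permutation of chromosomes does not allow for it. Among unshared peaks alone, Pearson's r was 0.80 (permutation p = 2e-05), or 0.72 without the same pair of chromosomes, and Spearman's rho was 0.81 (permutation p = 3e-05). The share of biotin peaks with an antibody partner did not differ detectably between chromosomes (permutation p = 0.524, 10000 permutations).

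**Figure D4:**
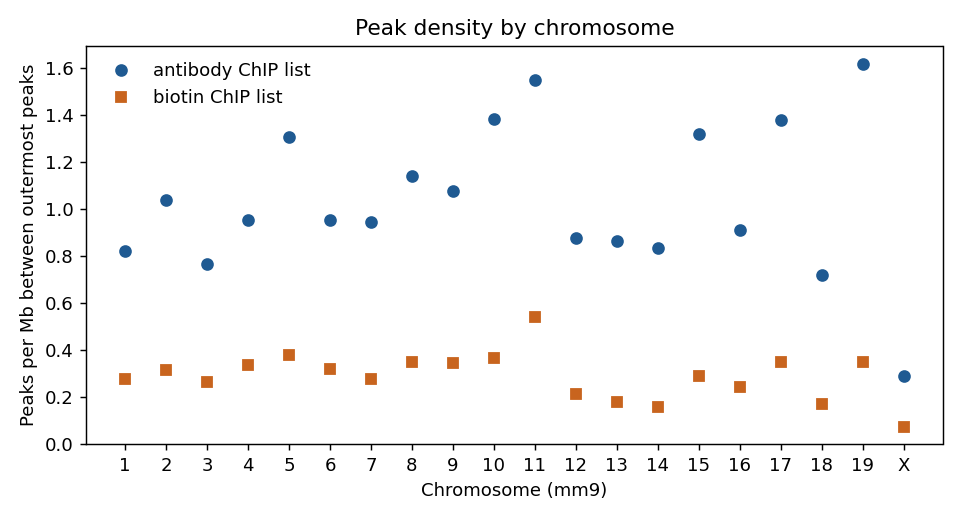
Peaks per Mb of the span between the outermost peaks of each chromosome (y axis) for chromosomes 1 to 19 and X of mm9 (x axis); circles are the antibody list and squares the biotin list. Density is lowest on chromosome X in both lists, at 0.289 and 0.0723 peaks per Mb.

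The list deposited with the antibody input held 682 intervals and no signal of an input library. Each was identical in position, fold, p-value and summit to a peak of a ChIP list, 341 to antibody peaks and 341 to biotin peaks. It contained every shared peak of both lists and 0 unshared ones, so the deposited common set equals the set obtained here with an overlap of at least 1 bp.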

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

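No alternative reversed a direction. The overlap exceeded all 1000 placements (permutation p = 0.001) under each of the 7 settings fixed beforehand and the 3 added later. The share of antibody peaks ranged from 12.5% with an overlap of 50% of the shorter peak to 18.2% in the top 25% of each list, and it was 33.9% with an antibody list of the same length as the biotin list. The share of biotin peaks ranged from 42.3% without peaks that have a neighbour within 1000 bp to 63.0% in the top 25% of each list, apart from the 33.9% with equal lengths. The fold difference stayed past the threshold in every setting tried (8.22 to 9.53 in the antibody list, 1.58 to 1.85 in the biotin list). The width difference passed the unadjusted threshold with centres within 200 bp (-7 bp in the antibody list, p = 0.0301 by permutation), with peaks within 1000 bp (-8 bp, p = 0.0057 by permutation) and with an overlap of 50% of the shorter peak (8 bp in the biotin list, p = 0.0353 by permutation). The cause was not tested. In the antibody list the width difference was 0 bp with an overlap of 50% of the shorter peak. It was also 0 bp without peaks that have a neighbour within 1000 bp. With an overlap of at least 50% of the shorter interval, 91.8% of the deposited common set met both lists, against 100% with 1 bp, which follows from the stricter definition. The settings listed beforehand for promoters, motifs and gene lists were not run, as no annotation of mm9 was used here. No paired analysis was possible because each group has 1 library, and no replicate could be left out. The unknown depth limits every statement on a peak that is missing from a list, since reads at that site were not analysed here.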

Other observations

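The regions described first and the tests of narrow calls, of nearness to the p-value limit, of distances within and between lists and of p-value ranks in this part were chosen after related values had been seen.

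Some regions held several peaks of both lists. Joining peaks with gaps of at most 10 kb gave 2533 regions, of which 407 held peaks of both lists, 1846 antibody peaks only and 280 biotin peaks only. The region with the most peaks was on chromosome 4 (32325633 to 32345396, mm9), with 5 antibody and 2 biotin peaks, folds of up to 21.8 and 10.2, and 2 shared pairs. A region on chromosome 1 (130499074 to 130511646) held 4 antibody and 2 biotin peaks with folds of up to 22.1 and 19.6. Regions on chromosome 4 (48047366 to 48057494) and chromosome 11 (96839212 to 96857972) held 4 antibody peaks each and 0 biotin peaks. Of the 22 regions with 3 or more antibody peaks, 13 (59.1%) held a biotin peak. Among the 2027 regions with 1 antibody peak, 322 (15.9%) did. This contrast was not tested. Part of it is built in, since a region with more antibody peaks has more chances to hold a biotin peak. Regions were also joined over peaks of both lists, so a biotin peak can link antibody peaks into a single region.

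Neighbouring peaks within a list were closer than random placement gave. In the antibody list, 252 neighbouring pairs started within 10 kb of each other, against a mean of 26.7 and at most 45 in 1000 random placements (one-sided permutation p = 0.001). In the biotin list there were 36 such pairs against a mean of 2.26 and at most 8 (one-sided permutation p = 0.001). Of these pairs, 111 in the antibody list and 20 in the biotin list started within 1 kb of each other. Whether such near pairs are separate sites or parts of 1 site was not tested. Random placement also ignores chromatin accessibility and mappability. Of all biotin peaks, 56.0% had an antibody peak within 1 kb and 76.5% within 100 kb, against 0.217% and 14.8% on average for shifted peaks. Both shares include the 341 biotin peaks (47.2%) that overlap an antibody peak, so they largely restate the overlap.

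The first pattern is the 382 biotin peaks without an antibody peak. Narrow calls that miss each other cannot account for most of them, since 64 (16.8%, 13.1 to 20.9%) had an antibody peak within 1000 bp. Nearness to the calling limit of the biotin list could not be the whole account either. Of the 145 biotin peaks with a p-value listed as 0, the farthest from the p-value limit of the list, 62.1% (53.6 to 70.0%) were shared. That is below the 90% set for this explanation. Nearness to the limit stays open for part of the pattern, as 20.2% (13.1 to 28.9%) of the 109 peaks with a p-value above 1e-12 were shared; in the 25% of biotin peaks with the highest fold, 72.2% (65.1 to 78.6%) were, but a high fold alone does not place a peak far from that limit. A hypothesis that these peaks lie in the same neighbourhoods as antibody peaks was met by its test, though only for a minority of them. Of the 382 peaks, 92 (24.1%) had the nearest antibody peak 1 to 50 kb away. In 1000 local shifts of 200 kb to 1 Mb the mean was 51.3 and the highest count 73 (one-sided permutation p = 0.001). The 92 peaks may mark other sites in the same regulatory regions. Clustering of open chromatin on a scale under 200 kb would give the same count and was not tested. Differences between the mice, the isolation methods and their inputs also stay open and untested. So does antibody signal at these sites that stayed under the limit of the antibody list, which the tests above do not cover.

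The second pattern is the 2166 antibody peaks without a biotin peak. Narrow calls that miss each other cannot account for most of them, since 86 (3.97%, 3.19 to 4.88%) had a biotin peak within 1000 bp. A shorter reach of the biotin list may explain part of the pattern. The shared share rose with antibody fold but was 58.0% (51.6 to 64.2%) in the highest 10%, between the 50% that would have argued against this explanation and the 75% that would have met it. It cannot be told apart from binding by the antibody of sites that the tagged protein does not occupy, because biotin reads at these sites were not analysed here. The difference between the mice also stays open and untested.

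The unshared pairs on chromosome 17 combined high folds with p-values that were not among the smallest of the list. Of all biotin peaks, 68.7% and 66.1% had a smaller p-value than the pair at 39982236 and 39985257, which was also wider than 99.3% and 99.9% of biotin peaks. For the pair at 36368266 and 36368448 these shares of smaller p-values were 68.2% and 54.5%, but its peaks were narrow, at 54 and 6 bp, with 24.1% and 0.277% of biotin peaks narrower. None of the 4 is established as a binding site here, since repeated sequence, such as ribosomal DNA collapsed into a single copy in the build, was not checked for at these positions and stays open. The only mitochondrial peak was in the biotin list (15524 to 15596), with a fold of 18.0. It is likewise not established as a binding site here, as its source was not analysed.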
